A study of Homo sapiens with 6 samples.

How the data were processed

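Gene-level RNA-seq counts of 6 poly(A) libraries of BJ fibroblasts were used, 3 from cells kept for 48 h with 10% GSSG liposome and 3 from cells kept with a control liposome. The percentage stands in the name of the GSSG treatment, and the labels do not say whether it also applied to the control liposome. The deposited counts are integers per Ensembl gene, made by the authors with HISAT2 2.0.5 alignment to the human build hg38 and featureCounts 1.5.0-p3, per the submitters' processing notes. The settings of both tools are not given in the sources used here. The kit text in the labels describes both directional and non-directional libraries, so the strand setting of the counting is unknown, and overlapping genes could share or lose reads. The table held 58735 genes, of which 26865 had at least 1 count, and 58690 had the same coordinates as in GENCODE release 29 (Ensembl 94). Of the tested genes, 8152 were overlapped by another gene with reads, 4481 by one holding at least 10% as many reads, and 3687 by such a gene on the opposite strand. Where a gene named by the rule was overlapped by a gene with at least 10% as many reads, the share is given beside the result.

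The groups, the main test, the gene lists, the rule for naming genes and most of the alternatives were chosen before the data were examined. Genes were kept by edgeR's filterByExpr with its minimum count of 10 and minimum total of 15, which left 14641 genes, 12691 of them protein coding. Library sizes were scaled by the trimmed mean of M values, with factors of 0.969 to 0.975 in control and 1.03 in GSSG libraries. Dispersions were estimated and a quasi-likelihood F test was made per gene in edgeR 4.0.16, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. With 3 libraries per group the fit had 4 residual degrees of freedom before edgeR's moderation. CPM were computed from the scaled library sizes, and SE was computed from the SDs of log2 CPM with a prior count of 2. Where a group had fewer than 3 counts over its libraries, the summed counts and an exact binomial interval are given in place of the log2 fold change alone.

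Pairs of libraries were compared by a chi-square test per gene with at least 20 counts in the pair. The chi-square per gene and degree of freedom was 1.93 to 3.25 within groups and 72.5 to 101 between them, where sampling of reads alone gives 1. Correlations of log2 CPM were 0.992 to 0.993 within groups and 0.949 to 0.951 between them. The first principal component held 81.8% of the variance and separated the groups. On simulated counts of 14641 genes with the depth and dispersion of these libraries, the test recovered 22%, 66%, 88% and 98% of genes changed by 0.2, 0.5, 1 and 2 on the log2 scale, with 8 false calls (5.52% of calls). Only 50 genes were changed at each size, while 63.2% of genes were called in these data. Adjustment was therefore stricter in the simulation.

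Genes were named by a fixed rule. It takes the 8 largest rises and 8 largest falls among protein coding genes with an adjusted p under 0.05, a mean of at least 1 CPM and all 3 values of one group above those of the other. It adds up to 3 members of each list with the smallest p among those that passed. It also adds HSPA5, DDIT3, ATF4, XBP1, ERO1A, HMOX1, GCLM, GSR, CDKN1A, CDKN2A, LMNB1, MKI67 and IL6 whatever their p, and 9 fibroblast identity markers. RPS10, SLC30A1, KRT10, EPCAM, PTPRC, PMEL, KRT5 and TP63 in the results, and the genes named under other observations, were chosen after their values were seen. Some genes that the rule names are not reported here.

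The 28 fixed lists were written from general knowledge of ER proteostasis, stress responses, glutathione and metal handling, senescence, proliferation, matrix, lipids, lysosomes, interferon, hypoxia, ribosomes, mitochondria and markers of other cell types. The 26 with at least 3 tested members were compared with all other genes by camera in limma 3.58.1 on log2 CPM, with a preset inter-gene correlation of 0.01, and again with the correlation estimated per list. Estimating it from 6 libraries is imprecise, and camera then uses the 4 residual degrees of freedom in place of a number set by the genes. A larger p with an estimated correlation can come from either. Lists of the endothelial and the blood cell markers were too small for that test. A further 13 lists were written after the gene results were seen, and 26 transcription factor families were taken from a column of the deposited table. Both sets were adjusted each over itself and are given under other observations.

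Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, scaling by total counts only, no filter, a filter of 1 CPM in 3 libraries, a minimum fold of 1.5, an adjusted p under 0.01, the replicate number as a block, fry for the lists, and leaving out each library in turn. Offsets for gene length and GC content (natural splines with 5 degrees of freedom per property) and a test of protein coding genes only were added after the data were seen. The offsets were fitted to each library's deviation from the gene mean over all 6 libraries. They therefore also remove any real treatment change that follows length or GC content. Scripting used R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Reads were not used here, so the alignment, the strand setting and the identity of the libraries could not be checked from sequence.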

Results

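RNA-seq was done on BJ cells, an established line of normal human skin fibroblasts, that had been kept for 48 h with 10% GSSG liposome or with a control liposome. GSSG usually stands for glutathione disulfide, the oxidised form of glutathione, although the labels do not spell it out. There were 3 libraries per treatment and 6 in all. Total counts were 16421334, 23163969 and 18779007 in control libraries 1 to 3 and 20119583, 18939309 and 16834610 in GSSG libraries 1 to 3. The series concerns endoplasmic reticulum (ER) proteostasis in senescent cells and vanadyl sulfate as a senolytic compound. The comparison made here asks which transcripts differed between fibroblasts given GSSG liposome and those given control liposome. Untreated cells and vanadyl sulfate were not analysed here. The labels number the 3 libraries of a treatment as replicates without saying that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Log2 fold changes are GSSG over control, levels are counts scaled to library size (CPM) as mean ± SD of 3 libraries, and SE is the standard error of the log2 fold change.

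Genes of DNA replication and mitosis were far higher in the GSSG libraries, and interferon response genes were lower. Most ribosomal protein genes (58 of 59) and matrix genes (27 of 35) fell too, but their list calls were lost, at camera adjusted p = 0.346 and 0.231 with an estimated correlation. MKI67, the proliferation antigen Ki-67, went from 12.8 ± 0.741 to 175 ± 1.91 CPM, a 13.7-fold rise. COL1A1, the most abundant fibrillar collagen chain of fibroblasts, went from 25118 ± 169 to 15989 ± 360.1 CPM, a log2 fold change of -0.65. The largest rise among protein coding genes with a mean of at least 1 CPM was that of ESM1, which encodes the secreted proteoglycan endocan and lies (ENSG00000164283) on chromosome 5 from 54977864 to 55022671 of hg38. It went from 1.07 ± 0.226 to 48.2 ± 3.34 CPM (log2 fold change 5.45, SE 0.18, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 4.53e-27). Next came GPR137C (4.76), CLSPN (4.51), an adaptor of the replication checkpoint, FAM111B (4.41) and E2F7 (4.41), a repressor of the E2F family. PODXL (4.41), ESCO2 (4.32), an acetyltransferase of cohesin, and FBXO43 (4.32) completed the 8 largest rises. Their order is uncertain, since values moved when 1 library was left out, most for GPR137C (4.22 to 5.81), which rested on 9 counts in control libraries, and also for PODXL (4.17 to 5.09) and FBXO43 (3.86 to 4.73). CCDC25, on the opposite strand to ESCO2, held 269% as many reads as ESCO2 itself.

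Among the largest falls by the same rule, C10orf105 was near absence with GSSG. It had 180 counts over the control libraries and 2 over the GSSG libraries, a ratio of 91.1 with a 95% exact interval of 24.9 to 758 that covers counting error only. SCN1A (log2 fold change -4.13), a sodium channel gene, and FMO1 (-3.40), a flavin-containing monooxygenase gene, were also low in both treatments, at a mean below 5 CPM. They rested on 12 and 22 counts in GSSG libraries and ranged from -4.72 to -3.67 and from -4.03 to -3.09 when 1 library was left out. More abundant genes were MAP2K6, a kinase upstream of p38, which went from 22.4 ± 1.28 to 1.61 ± 0.442 CPM, and FAM198B, which went from 44.5 ± 2.05 to 4.92 ± 0.251 CPM. CPA4, a carboxypeptidase gene (ENSG00000128510) on chromosome 7 from 130293134 to 130324180, went from 171 ± 2.57 to 19.1 ± 0.488 CPM (log2 fold change -3.17, SE 0.024, edgeR adjusted p = 1.96e-31).

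Of 14641 genes tested, 4715 were higher and 4541 lower with GSSG liposome at an adjusted p under 0.05 in edgeR's quasi-likelihood test, which is 63.2% of the genes. Most of the changes were small. The log2 fold change was at least 1 in size in 1028 of the higher and 891 of the lower genes, and 159 and 22 genes changed at least 8-fold. In 9746 genes (66.6%) the 3 values of one treatment all lay above the 3 of the other, against 10% by chance. Every gene named here as higher or lower by its test was separated in that way. The median log2 fold change of all genes was -0.0023, and the common coefficient of variation between libraries was 3.72%. Against a minimum change of 1.5-fold, 1314 genes were higher and 1065 lower.

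**Figure D1:**
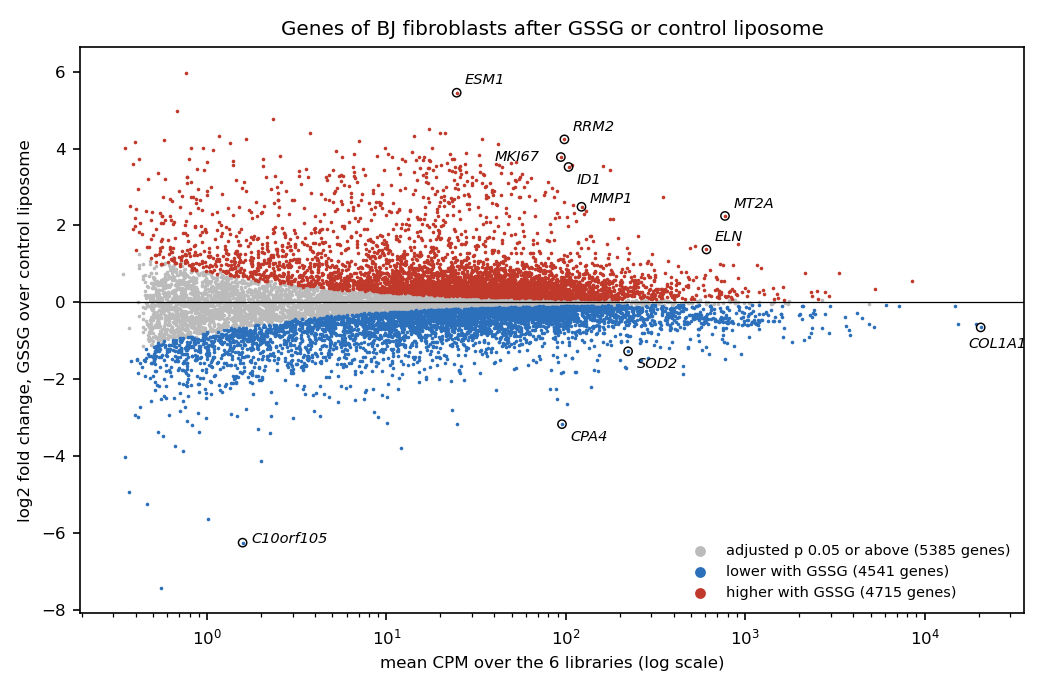
Log2 fold change of each tested gene, GSSG over control liposome, against its mean CPM over the 6 libraries on a log scale. Red points are the 4715 genes that were higher, blue points the 4541 that were lower and grey points the 5385 with an adjusted p of 0.05 or above in edgeR's test, and circles mark named genes such as ESM1 at 5.45 and CPA4 at -3.17.

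Gene lists fixed in advance covered the processes that a redox, ER stress or senescence experiment in fibroblasts would address. Of 28 lists, 26 had at least 3 tested members and entered camera, which compares a list with all other genes. 6 lists were higher, 6 lower and 14 not called at an adjusted p under 0.05, with Benjamini-Hochberg adjustment over the 26. With an inter-gene correlation estimated per list in place of the preset 0.01, DNA replication, mitosis and interferon response kept their calls. That form of the test also has only 4 residual degrees of freedom, so a lost call need not come from correlation between genes. The metallothionein list, estimated at -0.073, lost its call too. With the preset value, each of the 9 other splits of the libraries into 3 and 3 also gave called lists, 2 to 7 in one direction and 2 to 4 in the other. Part of the treatment difference remains in those splits. Member counts adjusted over the list alone were the same as those over all genes in 23 of the 28 lists, and are given beside the other 5.

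All 39 members of the DNA replication list rose, each at least 2-fold, with a median log2 fold change of 2.63. RRM2, the small subunit of ribonucleotide reductase, went from 9.89 ± 0.281 to 187 ± 1.59 CPM (log2 fold change 4.24, SE 0.024, edgeR adjusted p = 1.62e-33). UHRF1, which guides maintenance DNA methylation, and MCM4, a subunit of the replicative helicase, rose with log2 fold changes of 2.97 and 2.75. All 38 members of the mitosis list rose as well, with a median of 3.14. ANLN, which encodes the cytokinesis protein anillin, went from 25.4 ± 1.11 to 297 ± 5.75 CPM, and TOP2A, topoisomerase II alpha, from 29.8 ± 1.12 to 324 ± 8.41 CPM. The camera adjusted p was 3.70e-20 for DNA replication and 1.26e-22 for mitosis, and both had an adjusted p of 0.00481 with an estimated correlation.

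Of the genes used as markers of senescence, LMNB1 rose, CDKN1A and CDKN2A fell, and the secretory factors went both ways. LMNB1, the lamin B1 gene whose transcript falls in senescent cells, rose from 11.7 ± 0.782 to 92.7 ± 1.83 CPM (log2 fold change 2.99, SE 0.057). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, fell from 545 ± 10.2 to 488 ± 15.3 CPM, and CDKN2A, which encodes p16 and ARF, fell from 24.1 ± 0.413 to 17.0 ± 2.44 CPM. Their edgeR adjusted p were 2.21e-05 and 7.55e-06. The log2 fold change of CDKN1A, -0.16, was -0.080 with scaling by total counts and -0.060 with offsets for gene length and GC content. Of 35 tested senescence secretory factors, 19 rose, 13 fell and 3 did not pass the test. MMP1, an interstitial collagenase, rose from 37.1 ± 1.46 to 208 ± 2.88 CPM and SERPINE2 had a log2 fold change of 0.96, while IGFBP4 (-0.84) and the cytokine gene IL6 (-0.60) fell. The list was not called (median 0.40, camera adjusted p = 0.234).

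Of 27 p53 targets, 7 rose, 12 fell and 8 did not pass the test. PMAIP1, the NOXA gene, rose (2.02) and CCNG1 fell (-0.78). POLH, a translesion polymerase gene, rose (1.15), although GTPBP2 on the opposite strand held 367% as many reads. The p53 list had a median of -0.10, a mean of 0.057 and a camera direction of down that did not pass (adjusted p = 0.703).

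Of 24 ER chaperones and regulators of the unfolded protein response, 17 rose, 3 fell and 4 did not pass the test. HSPA5, the main ER chaperone BiP, did not pass and measured 1196 ± 10.8 CPM in control and 1204 ± 14.3 CPM in GSSG libraries (log2 fold change 0.0099, SE 0.012, edgeR adjusted p = 0.751). Its value was 0.090 (adjusted p = 0.00190) with scaling by total counts and -0.056 (adjusted p = 0.0259) with length and GC offsets, in a range of adjusted p from 0.00190 to 0.963 over 14 alternatives. PDIA4, an ER protein disulfide isomerase, went from 249 ± 0.775 to 370.4 ± 1.12 CPM, and CREB3L2, an ER-anchored transcription factor, and DNAJC10, an ER disulfide reductase, had log2 fold changes of 0.78 and 0.68, the latter 0.43 with length and GC offsets. XBP1, a transcription factor of the response, fell with a log2 fold change of -0.15 (edgeR adjusted p = 4.07e-04). The XBP1 value was -0.071 (adjusted p = 0.0795) with total counts and -0.35 with length and GC offsets, in a range of adjusted p from 9.98e-11 to 0.0795 over 14 alternatives. The list had a median of 0.30 and a camera adjusted p of 0.00366, which became an adjusted p of 0.231 with an estimated correlation. With length and GC offsets the median was 0.10 and the adjusted p 0.0191.

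Among 25 tested genes of ER-associated degradation, 15 rose, 5 fell and 5 did not pass the test. UGGT1, the glucosyltransferase that senses misfolded glycoproteins, rose (0.83), as did VCP (0.42), the segregase that extracts substrates, and the lectin gene OS9 fell (-0.47). The list was not called (median 0.20, camera adjusted p = 0.0621). It was called with total counts at an adjusted p of 0.0355, in a range from 0.0355 to 0.414 over 12 alternatives. Of 19 genes of ER oxidative folding, 9 rose, 6 fell and 4 did not pass, or 9 and 7 adjusted over the list alone. The oxidase gene ERO1A went from 173 ± 7.23 to 235 ± 6.74 CPM, and the thioredoxin-related genes TMX3 (0.46) and TMX1 (0.50) also rose. These 3 log2 fold changes, the first of them 0.44, were 0.18, 0.18 and 0.22 with length and GC offsets. The list had a median of 0.018 and a camera adjusted p of 0.603.

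Targets of the integrated stress response went both ways, with 12 of 29 higher, 12 lower and 5 not passing, or 12 and 13 adjusted over the list alone (camera adjusted p = 0.846). ATF4, the central transcription factor of that response, fell from 593 ± 16.2 to 458 ± 9.63 CPM. DDIT3, which encodes CHOP, fell with a log2 fold change of -0.33 (edgeR adjusted p = 2.61e-04), and MARS, which overlaps it on the opposite strand, held 810.3% as many reads. The amino acid transporter genes SLC7A1 (1.18) and SLC7A5 (0.76) rose and NUPR1 (-0.96) fell. Of 18 aminoacyl-tRNA synthetases, 5 rose, 4 fell and 9 did not pass (median -0.032, camera adjusted p = 0.911). QARS (-0.63), WARS (-0.37) and AARS (-0.32) were among those that fell.

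In the list of heat shock genes, which encode mainly cytosolic chaperones, 11 of 22 rose, 2 fell and 9 did not pass. HSP90AA1, the inducible HSP90, went from 575 ± 17.6 to 1136 ± 11.7 CPM and HSPA8 had a log2 fold change of 0.64, while SERPINH1, which encodes the collagen chaperone HSP47, fell from 2111 ± 6.45 to 1128 ± 21.7 CPM. The list median was 0.20 and the camera adjusted p 0.0185, or an adjusted p of 0.337 with an estimated correlation. Of 31 proteasome subunits, 20 rose, 2 fell and 9 did not pass. PSMD2 went from 177 ± 4.01 to 425 ± 3.89 CPM and PSMA5 fell to 92.3 ± 2.21 from 183 ± 5.65 CPM. PSMD14 rose (0.74), with a processed pseudogene on the opposite strand holding 26.1% as many reads. The list median was 0.18, or 0.10 with length and GC offsets, and the camera adjusted p 0.00375, which became an adjusted p of 0.444 with an estimated correlation.

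Genes of glutathione metabolism split evenly, with 15 of 35 higher, 15 lower and 5 not passing (median -0.00056, camera adjusted p = 0.846). GSR, which encodes the reductase that turns GSSG back into glutathione, measured 47.4 ± 0.681 CPM in control and 47.3 ± 1.39 CPM in GSSG libraries. Its log2 fold change was -0.00056 (SE 0.027, edgeR adjusted p = 0.994) and 0.080 with total counts, in a range of adjusted p from 0.198 to 0.989 over 14 alternatives. ANPEP, an aminopeptidase that acts on glutathione breakdown products, and GSTO1, an omega-class transferase, rose with log2 fold changes of 0.70 and 0.85. GPX1, glutathione peroxidase 1, fell (-0.60, or -0.35 with length and GC offsets). GCLM, a subunit of the enzyme that limits glutathione synthesis, was higher (0.18, edgeR adjusted p = 7.51e-04), but lower at -0.098 (adjusted p = 0.0391) with length and GC offsets. Its adjusted p ranged from 7.19e-06 to 0.0391 over 14 alternatives.

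Of 28 tested NRF2 targets, 10 rose, 11 fell and 7 did not pass, or 10 and 14 adjusted over the list alone (median -0.071, camera adjusted p = 0.322). HMOX1, heme oxygenase 1, rose from 50.5 ± 1.31 to 70.1 ± 3.07 CPM. The ferritin genes FTL (-0.79) and FTH1 (-0.66) fell, as did TKT (-0.73), the transketolase gene of the pentose phosphate pathway. Of 21 genes of peroxide and superoxide scavenging, 5 rose, 12 fell and 4 did not pass, or 5 and 13 adjusted over the list alone. SOD2, mitochondrial superoxide dismutase, fell from 315 ± 7.55 to 130.2 ± 2.20 CPM, with WTAP on the opposite strand holding 26.4% as many reads. SOD3 (-1.12) and TXNIP (-0.63), an inhibitor of thioredoxin, fell too. The list had a median of -0.22, or -0.14 with total counts, and a camera adjusted p of 0.0423, which became an adjusted p of 0.238 with an estimated correlation and 0.111 with length and GC offsets. Without control library 2, GSSG library 1 or GSSG library 3 it was 0.0547, 0.0541 and 0.0654, in a range from 0.0300 to 0.238 over 12 alternatives.

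In the list of metallothioneins, which bind zinc and copper, and zinc export, 6 of 7 tested members rose and 1 did not pass the test. The member for zinc export was SLC30A1, which rose with a log2 fold change of 0.47. MT2A (ENSG00000125148), on chromosome 16 from 56608199 to 56609497, went from 268 ± 10.2 to 1275 ± 38.4 CPM (log2 fold change 2.25, SE 0.041, edgeR adjusted p = 4.01e-32). MT1E rose with a log2 fold change of 0.89 and MT1L, annotated as a transcribed pseudogene, with 1.37. Metallothionein genes are near-identical copies, so reads may have been split or lost between them. The list median was 1.37 and the camera adjusted p 0.00366, which became an adjusted p of 0.185 with an estimated correlation.

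**Figure D2:**
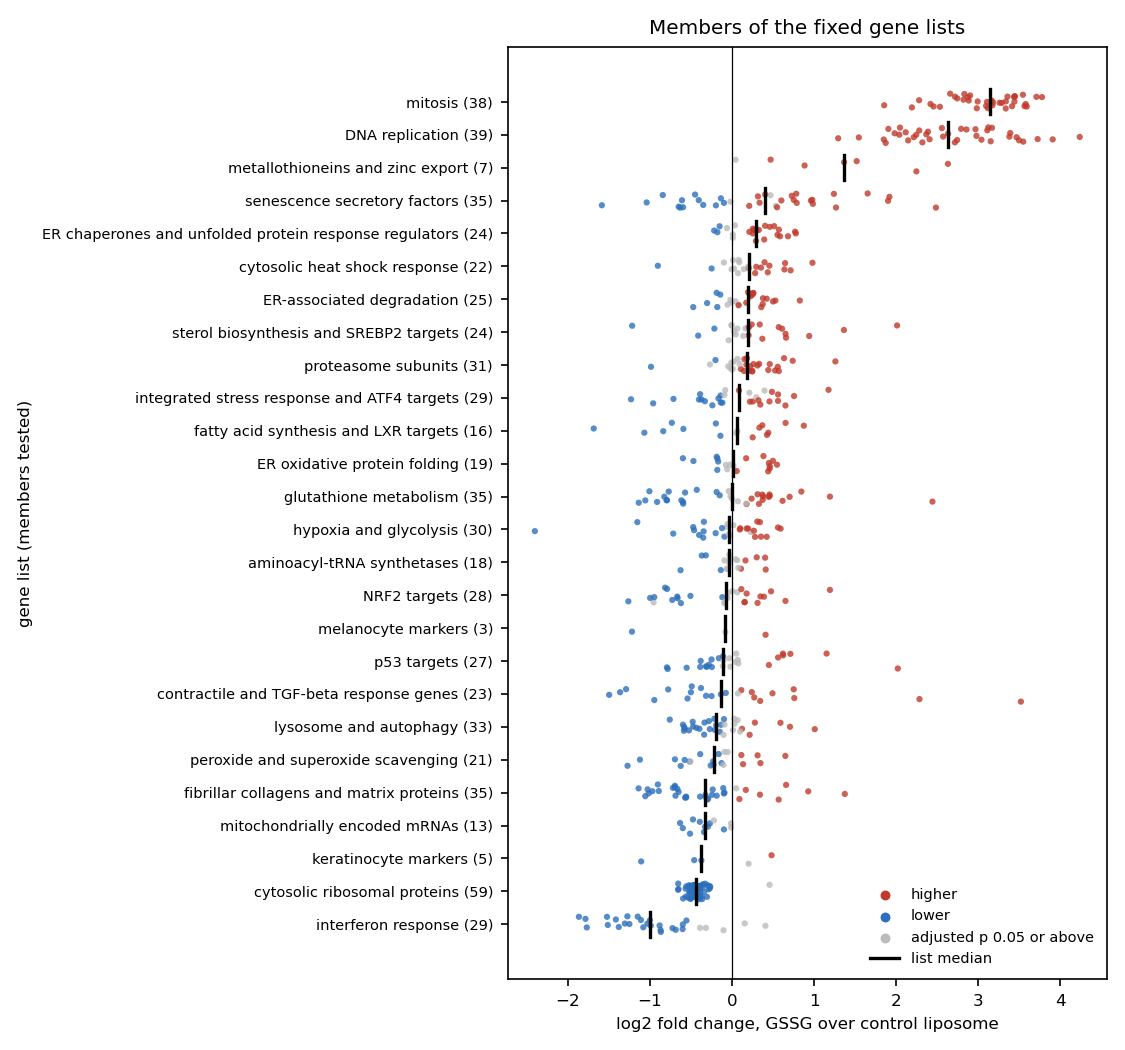
Log2 fold change, GSSG over control liposome, of the tested members of the 26 fixed gene lists with at least 3 tested members. Each point is a gene, red where it was higher, blue where lower and grey where its adjusted p was 0.05 or above, black bars are list medians, and the points of mitosis and DNA replication all lie to the right of 0 with medians of 3.14 and 2.63.

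Of 35 collagens and other extracellular matrix genes, 27 fell, 7 rose and 1 did not pass. The list median was -0.32 and the camera adjusted p 0.000107, or an adjusted p of 0.231 with an estimated correlation. DCN, the decorin gene, went from 1072 ± 6.62 to 515 ± 8.90 CPM and FBLN1, the fibulin 1 gene, from 2826 ± 63.2 to 1442 ± 23.5 CPM. ELN, which encodes elastin, moved the other way, from 339 ± 1.56 to 879 ± 18.3 CPM (log2 fold change 1.38, SE 0.018, edgeR adjusted p = 5.53e-28). Of 23 contractile and TGF-beta response genes, 9 rose, 13 fell and 1 did not pass. ID1, an inhibitor of basic helix-loop-helix factors, rose from 16.6 ± 2.21 to 191 ± 10.6 CPM and ID3 had a log2 fold change of 2.29, while CNN2, which encodes calponin 2, fell (-0.95). ID1 and ID3 are known targets of BMP signalling. The median was -0.13, the mean 0.013 and the camera direction down without passing (adjusted p = 0.422).

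Of 24 tested genes of sterol synthesis and SREBP2, 12 rose, 3 fell and 9 did not pass the test. EBP (1.36), an enzyme gene of late cholesterol synthesis, rose, and so did ACAT2 (2.01), although TCP1 on the opposite strand held 1233% as many reads. The list had a median of 0.19 and a camera adjusted p of 0.0589. It was called with total counts (adjusted p = 0.0399) and without GSSG library 2 (0.0436), in a range from 0.0399 to 0.238 over 12 alternatives. In the list of fatty acid synthesis and LXR targets 7 of 16 rose, 7 fell and 2 did not pass. The desaturase gene FADS1 (0.65), overlapped by FADS2 with 194% as many reads, and ACLY (0.44) rose, and the cholesterol exporter gene ABCA1 (-0.84) fell. That list had a median of 0.060, a mean of -0.11 and a camera direction of up that did not pass (adjusted p = 0.909).

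Lysosome and autophagy genes were lower in 20 of 33 cases, higher in 6 and did not pass in 7. PSAP, the saposin precursor, went from 1247 ± 4.36 to 832 ± 9.01 CPM, and CTSA (-0.47), a lysosomal carboxypeptidase gene, and GABARAPL1 (-0.48), an autophagosome component, fell. The median was -0.19, or -0.11 with total counts, and the camera adjusted p 0.0185, which became an adjusted p of 0.337 with an estimated correlation. Of 30 genes of hypoxia and glycolysis, 12 rose, 12 fell and 6 did not pass, or 12 and 13 adjusted over the list alone (median -0.031, camera adjusted p = 0.806). ADM, which encodes adrenomedullin, fell from 831 ± 28.2 to 374 ± 16.8 CPM and NDRG1 fell as well (-0.72). PDK1, a kinase that holds back pyruvate oxidation, rose (0.59, or 0.35 with length and GC offsets).

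Interferon response genes were lower in 24 of 29 tested cases, and 5 did not pass the test. IFITM3, a membrane protein that restricts virus entry, went from 1023 ± 42.5 to 501 ± 6.11 CPM (log2 fold change -1.03, SE 0.036, edgeR adjusted p = 3.37e-24). IFI6 (-0.87) and IFITM1 (-1.11) fell too, and IFITM2, which overlaps IFITM1 on the same strand, held 269% as many reads. The list median was -1.0 and the camera adjusted p 6.98e-09, or an adjusted p of 0.02003 with an estimated correlation.

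Cytosolic ribosomal protein transcripts fell in 58 of 59 cases, by similar amounts. RPL3 went from 2882 ± 72.9 to 1829 ± 25.2 CPM, and RPL13A and RPL12 had log2 fold changes of -0.66 and -0.65. RPS10, with a mean of only 0.570 CPM in control libraries, had a log2 fold change of 0.46 and did not pass the test (edgeR adjusted p = 0.39). Many of these genes have processed pseudogenes that can take some of their reads. The list median was -0.44 and the camera adjusted p 1.59e-14, which became an adjusted p of 0.346 with an estimated correlation. That correlation, 0.614, is between members across libraries within a treatment and does not measure how alike their changes were. Transcripts of the mitochondrial genome fell in 10 of 13 cases and 3 did not pass. MT-CO1 went from 6325 ± 151 to 4079 ± 90.1 CPM, and MT-CYB (-0.60) and MT-CO3 (-0.48) fell, with MT-ATP6 on the same strand holding 67.7% as many reads as MT-CO3. This list had a median of -0.33 and a camera adjusted p of 0.00366, or an adjusted p of 0.421 with an estimated correlation. Counts on the mitochondrial genome made up 2.05%, 2.13% and 2.15% of the control libraries and 1.63%, 1.58% and 1.64% of the GSSG libraries. The 10 most abundant genes took 11.7%, 11.6% and 11.6% of the control counts and 9.83%, 9.91% and 9.85% of the GSSG counts.

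Both treatments showed fibroblast transcripts. The identity markers COL1A2 (23213 CPM in control and 15618 CPM in GSSG libraries), COL3A1 (2948 and 1575 CPM), VIM (3074 and 2496 CPM) and THY1 (824 and 635 CPM) were abundant in both and lower with GSSG. PDGFRA (-0.73), PDGFRB (-1.20) and S100A4 (-0.99) fell as well. Of 14 keratinocyte markers 5 were tested, of which PERP (-0.46), KRT17 (-1.11) and KRT10 (-0.37) fell, DSP (0.48) rose and EPCAM did not pass (camera adjusted p = 0.449). KRT5 and TP63, markers of basal keratinocytes, had no count in the 6 libraries. Of 10 endothelial markers, TEK rose from 1.59 ± 0.293 to 6.89 ± 0.205 CPM and EGFL7 fell (-0.52, or -0.28 with length and GC offsets). Of 12 blood cell and macrophage markers 2 were tested, with LAPTM5 at 1.09 ± 0.278 and 1.80 ± 0.422 CPM. LAPTM5 was higher (0.73, edgeR adjusted p = 0.0364), but not in DESeq2 (adjusted p = 0.138), nor without control library 2 (0.0754) or 3 (0.145) or GSSG library 2 (0.212) or 3 (0.0529), in a range from 0.0205 to 0.212 over 14 alternatives. PTPRC, at -0.40, did not pass. Of 8 melanocyte markers 3 were tested, of which KIT fell (-1.22), MITF rose (0.41, or 0.20 with length and GC offsets) and PMEL did not pass (camera adjusted p = 0.846).

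**Figure D3:**
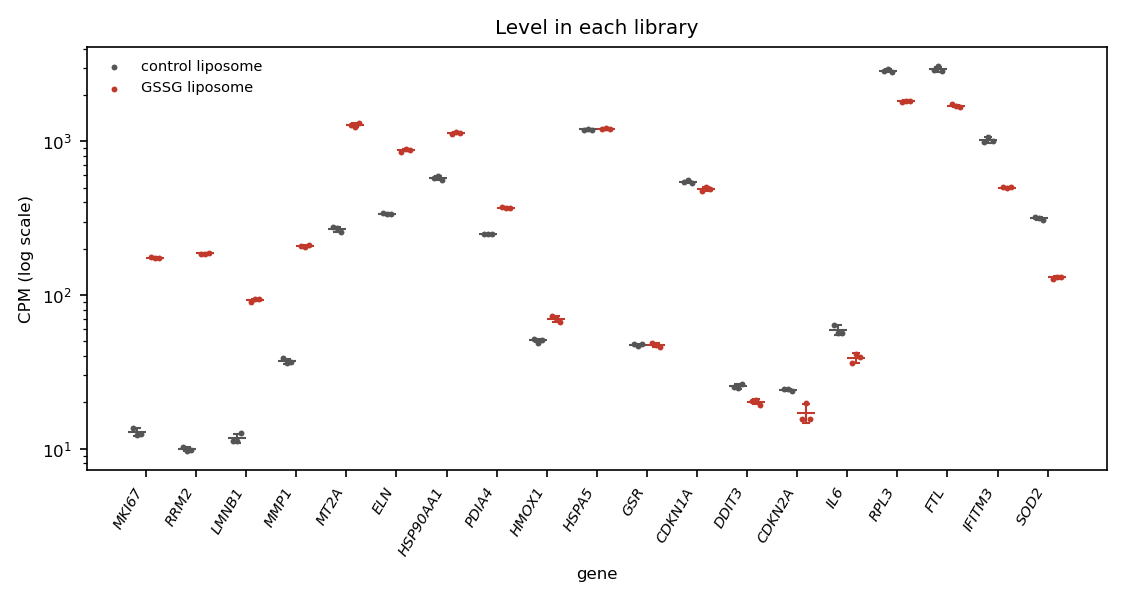
Level of named genes in each library, in CPM on a log scale, with grey points for the 3 control and red points for the 3 GSSG libraries, and a bar at the mean with whiskers of 1 SD. MKI67, RRM2 and LMNB1 lie higher with GSSG, RPL3, FTL, IFITM3 and SOD2 lower, and HSPA5 and GSR overlap.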

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

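Length and GC offsets and the restriction to protein coding genes were chosen after the data were seen. The number of genes higher with GSSG liposome, 4715, lay between 4083 and 5592 over the other settings, and the number lower, 4541, between 3742 and 5006, apart from the minimum fold of 1.5, where they were 1314 and 1065 because small changes no longer pass by construction. DESeq2 called 4179 and 3788 genes and limma-voom 4722 and 4558. Scaling by total counts gave 5592 and 3742, since it shifted the median gene to 0.078 from -0.0023. Length and GC offsets gave 4189 and 5006. Leaving out 1 library gave 4412 to 4559 higher and 4235 to 4394 lower genes. Of 1498 values of 107 named genes under 14 alternatives, 1481 kept their direction and side of the threshold, 6 kept the direction and lost the call, 1 gained a call and 10 changed sign.

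The changes of sign fell on HSPA5, GCLM and GSR, whose changes were small. HSPA5 was -0.0565 (edgeR adjusted p = 0.0259) and GCLM -0.0979 (adjusted p = 0.0391) with length and GC offsets, against 0.0099 and 0.18. Against -0.00056, GSR was 0.0049 in DESeq2, 0.00094 in limma-voom, 0.0796 with total counts and 0.0047 without the filter, and ranged from -0.0238 without GSSG_liposome replicate 1 to 0.0206 without GSSG_liposome replicate 3. With total counts the median gene moved in the same way, from -0.0023 to 0.078, so that value of GSR follows the scaling. The cause of the other changes of sign was not tested.

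The 6 higher and 6 lower lists became 2 and 1 with an estimated inter-gene correlation. They became 12 and 11 with fry, which asks whether the members shifted in one net direction and does not compare them with other genes. The other settings gave 6 to 8 higher and 5 or 6 lower lists. Of 338 list values, 310 were unchanged in call and in any called direction, and 14 lost and 14 gained a call. No called list changed direction, while the medians of 7 lists that were not called changed sign under at least 1 setting. The peroxide list was the one most often lost.

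With the replicate number as a block, 4711 genes were higher and 4529 lower, and 6 lists higher and 5 lower. The peroxide list had a camera adjusted p of 0.0508 with the replicate block, in a range from 0.0300 to 0.238. Residuals of same-numbered libraries had r of -0.012 to 0.0226 and 2 of 6 libraries correlated best with their own number, so the numbers were not treated as pairs.

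Gene length and GC content were related to the changes. The median log2 fold change went from -0.14 in the shortest of 5 equal groups of genes to 0.099 in the longest, and from 0.17 in the group lowest in GC to -0.18 in the highest (Spearman rho 0.133 and -0.236 across genes, which are not independent). Small changes may partly follow that trend, and the median of the ER chaperone list was 0.10 with length and GC offsets against 0.30 without. The offsets cannot tell a technical trend from a treatment effect that follows length or GC content, since they remove both. In the simulation 22% of changes of 0.2 were recovered, but only 50 genes were changed at each size. Adjustment is stricter there than in these data, where 63.2% of genes were called, so that share does not carry over. How many small changes were missed here, and the part of depth in this, was not tested.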

Other observations

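Lists written after the gene results were seen extended the picture of proliferation. All 27 kinetochore and condensin genes rose (median log2 fold change 2.60, camera adjusted p = 1.27e-14, or 0.0109 with an estimated correlation), among them NCAPG (4.12) and SMC4 (2.32). All 21 tested genes of homologous recombination and the Fanconi anaemia pathway rose (median 3.26, camera adjusted p = 1.24e-11, or 0.0187 with an estimated correlation), with RAD54L at 4.02, BRCA1 at 3.50 and FANCD2 at 3.31. Nucleolar ribosome biogenesis genes rose in 22 of 28 cases while 1 fell (median 0.40, camera adjusted p = 1.17e-04, or 0.164 with an estimated correlation), for example NOP56 (0.94) and LYAR (0.97). Immediate-early and related genes rose in 14 of 26 cases and fell in 5 (median 0.27, camera adjusted p = 0.0340), with FOSL1 at 2.32, SPRY4 at 1.47 and FOS at -0.81. That adjusted p was 0.147 with an estimated correlation and 0.0530 without control library 3. Of 44 replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, 8 were tested, and 1 rose and 4 fell (median -0.45, camera adjusted p = 0.165).

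Complement genes fell in 14 of 15 cases (median -0.97, camera adjusted p = 4.84e-05, or 0.0508 with an estimated correlation), with C1R at -1.23, C3 at -1.02 and CFD at -1.44; C4A and C4B are near-identical and share reads. Flavin-containing monooxygenases and aldehyde dehydrogenases fell in 8 of 13 cases and rose in 2 (median -0.71, camera adjusted p = 0.00417, or 0.206 with an estimated correlation), with ALDH1A1 at -1.46 and FMO4 at -2.59. Nuclear-encoded respiratory chain genes fell in 23 of 44 cases and rose in 5 (median -0.16, camera adjusted p = 0.0172). That adjusted p was 0.531 with an estimated correlation, 0.0768 with total counts (median -0.076), 0.0950 with length and GC offsets (median -0.091) and 0.0519 without control library 2. BMP and Wnt ligands and antagonists went both ways, with 6 of 22 higher and 12 lower (camera adjusted p = 0.0912), with GDF5 at -2.82, WNT2 at -2.80 and BMP4 at -2.41. Of 26 transcription factor families, STAT factors fell in 7 of 7 cases (camera adjusted p = 0.00685) and E2F factors rose in 7 of 10 (0.0105), both 0.308 with an estimated correlation, and the other 24 did not pass. Antisense transcripts fell in 158 and rose in 47 of 548 cases (median -0.32), and long intergenic RNAs fell in 140 and rose in 58 of 403 (median -0.32). Since the strand setting of the counting is unknown, counts of antisense transcripts may hold reads of the genes they overlap.

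Of the tests weighed next, those of exchanged libraries and whole groups and of blood cell RNA were chosen only after the results were seen, as were the lists of YAP targets, quiescence, 5' oligopyrimidine tract mRNAs and antigen presentation. The 77 replication and mitosis genes had a median log2 fold change of 2.97, and genes matched to them on length, GC content and level had 0.0182, which argues against a bias of that kind. All 6 libraries correlated best with their own group, which argues against an exchange of single libraries. An exchange of the labels of both whole groups would leave that count at 6 and stays open, and untreated cells or a measure of growth, which could help to settle it, were not analysed here. Lower cell density in the GSSG cultures also stays open, with YAP and TEAD targets at a median of 0.0408 (11 of 22 rose, 9 fell, camera adjusted p = 0.570). Fewer quiescent cells with GSSG could account for the rise. Quiescence and growth arrest genes had a median of -0.421 (14 of 20 fell, 1 rose, camera adjusted p = 1.50e-04, or 0.0436 with an estimated correlation), with GAS1 at -1.82, CDKN1C at -1.42 and CCNG2 at 0.29. Their fall does not tell this explanation from the others left open.

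Cytosolic ribosomal protein transcripts lay -0.370 from the median of genes matched on length, GC content and level. This argues against such a bias as the whole cause of their fall. The matched genes had a median of -0.069 and a lower quartile of -0.402, and the 59 members shared 465 distinct matches. How close these were in level was not checked, so a part of abundance in the fall stays open. Reads moved to the 70 tested pseudogenes do not account for the fall. Their summed level went from 2406 CPM in control to 1765 CPM in GSSG libraries, and that of the ribosomal protein genes from 49880 to 36238 CPM. The pseudogenes had a median of -0.360, with 38 lower and 2 higher. Their counts may themselves be reads of the ribosomal protein genes, so that median is not independent of the fall. Other mRNAs with a 5' terminal oligopyrimidine tract had a median of -0.444, with 16 of 18 lower (camera adjusted p = 1.04e-05, or 0.169 with an estimated correlation), for example EEF2 (-0.71) and EEF1A1 (-0.57). A change of that whole class of mRNAs may therefore underlie the fall, and whether it came from transcription, stability or a shift in the makeup of the mRNA pool was not tested.

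Genes matched to the interferon response genes had a median of -0.0192, against -1.0 for the list, which argues against a length, GC or abundance bias. RNA of blood cells in the control cultures does not account for it, since the highest of 11 blood cell and macrophage markers had a mean of 1.09 CPM in control libraries. Antigen presentation genes had a median of -0.454, with 13 of 15 lower and 1 higher (camera adjusted p = 1.50e-04, or 0.0436 with an estimated correlation), among them B2M (-0.45), HLA-E (-0.57) and PSMB9 (-1.14). Weaker interferon signalling with GSSG could account for both lists, but signalling itself was not measured.

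The 6 libraries can be split into 2 groups of 3 in 10 ways. The split by treatment gave 4715 genes higher and 4541 lower, and the highest count in any other split was 0 in both directions, so 1 of 10 splits was as large for each. In those 9 other splits edgeR gave 73 to 120 genes with an unadjusted p under 0.05, against 9699 for the treatment, and limma-voom called 0 genes, against 9280. Each of these splits mixes the treatments within its groups, so the treatment difference widens the spread that the tests use. Their low counts therefore do not measure what libraries without a treatment difference would give. The sides of the other splits have no order, so the larger of their 2 directions was taken for both counts. The treatment split gave 6 higher and 6 lower lists, and 2 of 10 splits were as large for each, with a highest other value of 7 (control libraries 1 and 3 and GSSG library 2 against the rest). All 9 other splits, with 0 genes called, still gave 2 to 7 lists in one direction and 2 to 4 in the other. Their groups hold unequal shares of the treatments, so part of the treatment difference remains between them. Which lists were called there is not given here. These calls therefore do not show whether the preset correlation calls lists without a treatment difference. With 10 splits the share cannot be under 0.05.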
